A study of Mus musculus with 4 samples.

How the data were processed

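RNA was measured in 4 libraries of C2C12 cells, a mouse myoblast line that forms multinucleate myotubes when serum is lowered. Per the labels' protocols, cells were transfected with 30 nM siRNA by Lipofectamine and kept for 48 h in differentiation medium with horse serum, and libraries were made with an Illumina TruSeq RNA kit. In 2 libraries the siRNA had a scrambled sequence and in the other 2 it was directed against Mef2a. The titles number the libraries of each group 1 and 2. Nothing in the labels says whether the libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

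The deposited values were FPKM (fragments per kilobase of transcript, scaled to the library's fragment total), given by the authors for each Ensembl transcript and library with its gene identifier, symbol and locus, per the file headers. The submitters' processing notes name CASAVA, Trimmomatic, TopHat, Bowtie and Cufflinks and the mouse build mm10, without versions. The annotation, the settings of each tool, the scaling between libraries and the rule by which transcripts were listed are not given in the sources used here. Each library listed the same 36231 transcripts of 13824 gene symbols. Of these transcripts, 1055 were at 0 in at least 1 library and 6 were at 0 in all 4. Transcript lengths, types and gene coordinates were taken from GENCODE mouse release M21, on the same build, in which 35238 transcripts (97.3%) were found by identifier. No transcript of the mitochondrial chromosome was listed, and some isoforms of listed genes were missing, so that a gene's value covers its listed transcripts alone. Reads that fit several near-identical genes can be split between them by such an estimate, and the processing notes do not say how they were treated. No use of strand was stated, so a gene and an overlapping or antisense gene cannot be told apart.

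Fragment counts were not used here, and sums of FPKM do not give depth, since the microRNA gene Mir5105 alone took nearly all of each sum. Relative depth was read from low values: among 600 genes with 1 listed transcript and low FPKM, the commonest ratio between libraries (counted within 0.3%) was taken as the ratio of their fragment totals. This holds only if FPKM carried no other scaling between libraries, which is not stated. Relative to scrambled replicate 1 the estimated depth was 1.05 in scrambled replicate 2, 0.849 in siMEF2A replicate 1 and 0.847 in siMEF2A replicate 2. The commonest ratio was shared by 18 to 21 of 588 to 595 genes. Absolute depth stayed unknown, so no counting interval was computed.

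FPKM of the transcripts of a symbol were summed, 26 symbols of small RNAs were left out, and genes with a mean of at least 1 FPKM over the 4 libraries were kept, which left 11824 genes. Values were used as deposited, without further scaling, as log2(FPKM + 1). A fold change on this scale understates the change of genes with low FPKM. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend, two-sided), and p-values were adjusted by Benjamini and Hochberg's method. A gene was called at an adjusted p under 0.05. Unless another tool is named, each adjusted p of a gene is from this limma fit, and log2 fold changes are siMEF2A minus scrambled. Means are given with the SD over the 2 libraries of a group, and differences with the standard error of the fit. The moderated test had 2 residual degrees of freedom and 29.0 prior ones. A gene's p therefore rests mostly on the spread between libraries pooled over genes of similar level.

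Before the data were examined, 30 lists of genes were written down, together with the tests, the alternatives and the rule for the genes to be named. Of these lists, 25 had at least 5 members tested and were compared with the remaining genes by limma's camera with a correlation preset at 0.01, adjusted over the 25 lists. Camera with a correlation estimated for each list was an alternative, and so was fry, which tests a list against no change and not against the remaining genes. The named genes were Mef2a, Mef2b, Mef2c, Mef2d and Dusp6, the 10 called genes with the largest rise and the 10 with the largest fall among those whose groups did not overlap, and up to 4 members of each list with the smallest p in the direction of the list. Results of 2 genes that the rule names are not reported here. Genes described outside this rule are said to have been chosen after their values were seen.

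The gene test was tested on simulated data with the means of the 11824 genes in this comparison. Spreads were drawn from the variance distribution that limma fitted, with noise independent between genes. Genes to be changed were drawn only from those above a minimum mean level. The test recovered 49.3% of 67 changes of 1.5-fold, 100% of 67 changes of 2-fold and 100% of 66 changes of 4-fold, with 8 false calls among 174. It made 0 calls where nothing was changed. As the noise followed the test's own model, these false calls do not cover shifts shared by many genes or unstable short features.

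The alternatives were 3 other scalings (median-ratio, upper-quartile and quantile), pseudocounts of 0.1 and 0.5, no filter on low values or a minimum mean of 5 FPKM, small RNA symbols kept, limma without a trend or with robust moderation, the replicate number as a block, each library left out in turn, and other thresholds. After the data had been seen, 3 more were added: genes with only short or small RNA transcripts (under 300 bases) also left out, protein-coding transcripts alone summed, and transcripts tested one by one. Further calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and 1 pair of sequences was compared with BLAST 2.17.0. The MEF2A binding sites that the series' design mentions were not analysed here.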

Results

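The data were FPKM values of 4 RNA-seq libraries from C2C12 myoblasts after 48 h in differentiation medium, 2 transfected with a scrambled siRNA and 2 with an siRNA against Mef2a (siMEF2A). Sequencing depth relative to scrambled replicate 1, estimated from low FPKM values, was 1.05 in scrambled replicate 2. It was 0.849 in siMEF2A replicate 1 and 0.847 in siMEF2A replicate 2. The estimate assumes that FPKM carried no other scaling between libraries, and absolute depth was unknown. Over the genes tested, Pearson's r between replicates across genes was 0.989 for scrambled and 0.986 for siMEF2A, where genes are not independent replicates. The comparison asked which genes change when the transcription factor MEF2A is silenced in differentiating myoblasts.

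Genes of the contractile apparatus fell together in siMEF2A, and no member of that list rose. Of 40 sarcomere genes tested, 29 fell, among them Myl4, a myosin light chain of embryonic muscle, at 23.8% of its scrambled level, and Myh3, the embryonic myosin heavy chain, at 33.0%. Genes of calcium handling, acetylcholine receptor subunits and muscle-type energy enzymes were also among the 156 genes that fell. Fewer genes rose, 48 in all, with the cytokine gene Il33 at 2.93 times and the water channel gene Aqp1 at 2.10 times their scrambled levels. Dusp6, the phosphatase gene named in the series' title, was at 131% of its scrambled level and did not pass the test.

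The targeted gene Mef2a (ENSMUSG00000030557, chromosome 7, 67231163 to 67372858, minus strand, mm10) was at 25.8 and 32.2 FPKM in the scrambled libraries and at 12.7 and 14.3 FPKM in the siMEF2A libraries. Its mean fell from 29.0 ± 4.52 to 13.5 ± 1.08 FPKM (SD, n = 2 each), which left 46.5% of the scrambled level. The log2 fold change was -1.05 (SE 0.15, limma adjusted p = 3.35e-05). Of its 5 listed transcripts, the most abundant one, which is protein-coding, was at 49.4% of the scrambled mean. Its relative Mef2d, which encodes another member of the MEF2 family, was at 31.3 ± 1.63 FPKM in scrambled and 29.4 ± 2.33 FPKM in siMEF2A, a log2 difference of -0.09 with overlapping groups (limma adjusted p = 1.0). Mef2c was listed with 1 transcript, at 0.400 and 0.533 FPKM in scrambled and 0.380 and 0.463 FPKM in siMEF2A. These values were under the minimum for a test and cover that transcript alone. Values of Mef2b were not analysed here.

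**Figure D1:**
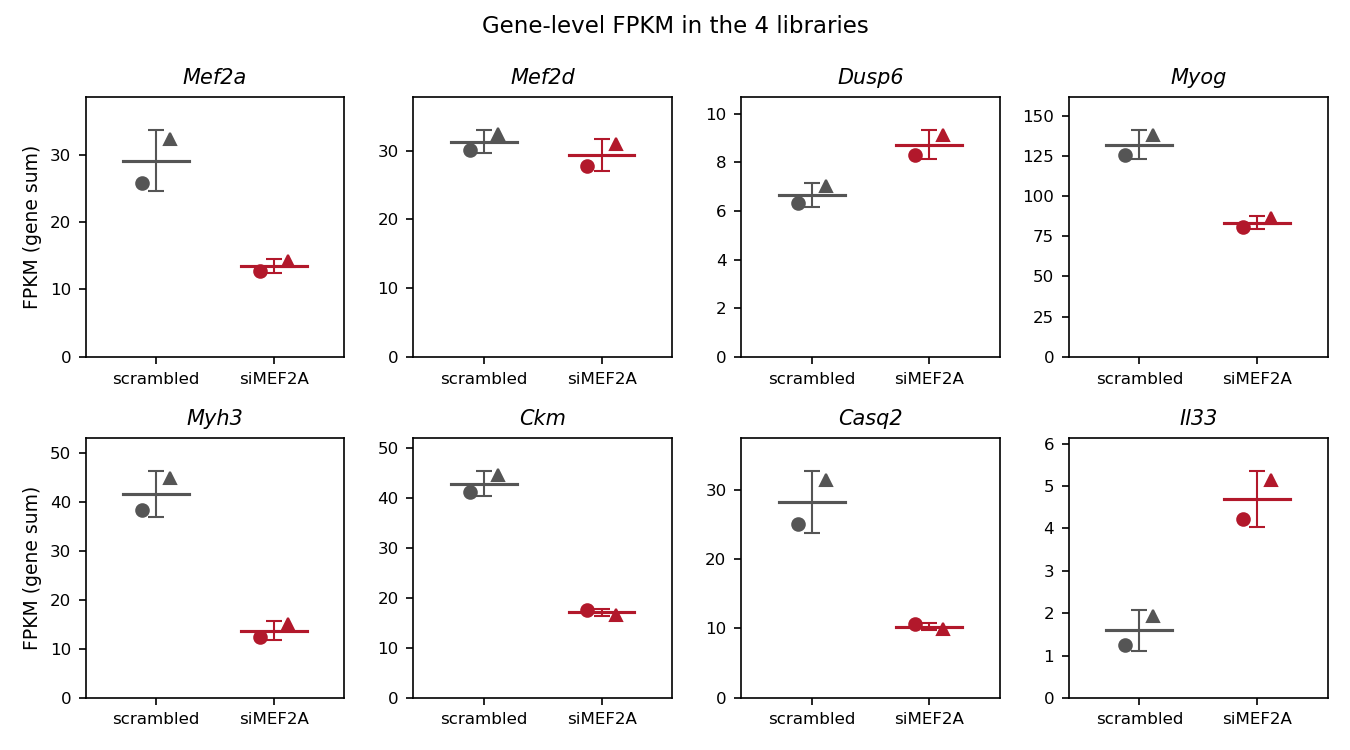
FPKM summed per gene for 8 genes in the 4 libraries (vertical axes start at 0; circles are replicate 1, triangles replicate 2, horizontal bars group means and error bars the SD over 2 libraries). Mef2a, Myog, Myh3, Ckm and Casq2 lie lower in both siMEF2A libraries, Il33 lies higher, Mef2d overlaps between the groups, and Dusp6, whose groups do not overlap, did not pass the test.

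Dusp6 (ENSMUSG00000019960, chromosome 10, 99263231 to 99267489, plus strand) encodes a phosphatase that inactivates ERK kinases. It was at 6.67 ± 0.485 FPKM in scrambled and 8.72 ± 0.595 FPKM in siMEF2A (SD, n = 2 each), higher in both siMEF2A libraries. The log2 fold change of 0.34 (SE 0.15) did not pass after adjustment (limma adjusted p = 0.592). With the replicate number as a block it passed (limma adjusted p = 0.0401), but the labels do not say that libraries pair. Among 17 dual-specificity phosphatase genes tested, 0 rose and 2 fell, and the counts adjusted over the list alone were also 0 and 2. Those that fell were Dusp27 at 49.2% and Dusp13 at 55.7% of scrambled, both genes of skeletal muscle, and Dusp4 was at 130% with an adjusted p of 0.556. The Dusp27 call was lost without scrambled replicate 2 (limma adjusted p = 0.0929) and without siMEF2A replicate 1 (0.183), and the Dusp13 call without scrambled replicate 1 (0.136), siMEF2A replicate 1 (0.0636) or siMEF2A replicate 2 (0.0790). Camera gave the phosphatase list an adjusted p of 0.373 in the lower direction, while its median log2 fold change was 0.05 and its mean -0.02. Of 22 MAP kinase genes, 0 passed the limma test and 1 had an unadjusted p under 0.05, Mapk14, the gene of p38 alpha, at 129% of scrambled with an adjusted p of 0.550 (camera adjusted p = 0.302 for the list). Of 33 immediate-early and ERK-responsive genes, 1 rose and 0 fell, with the same counts adjusted over the list alone. It was Egr2, a zinc finger transcription factor, which went from 0.947 ± 0.213 to 1.89 ± 0.188 FPKM (limma adjusted p = 0.0340), and that call was lost under each of the 3 other scalings (0.117 to 0.154) and without scrambled replicate 2 (0.322) or siMEF2A replicate 2 (0.132). It was also lost with a pseudocount of 0.1 (0.0528), with small RNA symbols kept (0.0583) and without a trend (0.0698). Camera gave this list an adjusted p of 0.0626, and an adjusted p of 0.834 with an estimated correlation, and called it higher under median-ratio (0.0452) and upper-quartile (0.0466) scaling and without a filter on low values (0.0381). With the replicate block camera also called the list higher (0.0490), and limma called Dusp4 (0.0395) and Mapk14 (0.0472) higher. The immediate-early list itself holds Dusp4, Dusp5 and Dusp6, so its result is not independent of theirs. Of 21 MEF2 cofactor and class IIa histone deacetylase genes 0 passed limma and 3 had an unadjusted p under 0.05, the smallest p in the direction of the list being that of Mbnl3 (limma adjusted p = 0.542, camera adjusted p = 0.431 for the list).

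Over all 11824 genes tested, 204 passed at an adjusted p under 0.05 in limma, 48 higher and 156 lower in siMEF2A, so that 76.5% of calls were lower. Scaling the libraries by median ratios gave 13 higher and 131 lower (91.0% lower), and upper-quartile scaling gave 14 and 132. Quantile normalization gave 11 and 107. Without scrambled replicate 2, some of the 204 calls were lost and other genes were called. At least a 2-fold change on the log2(FPKM + 1) scale was seen in 11 of the higher and 60 of the lower genes. Percentages of scrambled are ratios of mean FPKM and can pass 2-fold where this scale does not, as for Aqp1 (210%, log2 fold change 0.98). Among protein-coding genes, the largest falls on the log2(FPKM + 1) scale were those of Myl4, from 278 ± 15.0 to 66.0 ± 1.14 FPKM, and of Mb, the oxygen-binding protein myoglobin, from 21.3 ± 0.144 to 5.24 ± 0.787 FPKM. They were followed by Myoz2, which encodes a Z-disc protein that binds calcineurin, at 22.1% of scrambled, Tceal7 with a log2 fold change of -1.83 and Smpx, a small muscle protein gene of the X chromosome, at 22.5% of scrambled. For these 5 genes the limma adjusted p was at most 7.65e-10 and the log2 fold changes ran from -2.06 to -1.82.

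Among the genes that rose, Il33, an alarmin cytokine, was at 1.25 and 1.94 FPKM in scrambled and at 4.21 and 5.15 FPKM in siMEF2A (log2 fold change 1.14, SE 0.16, limma adjusted p = 1.12e-05). Pi15, a gene of a secreted peptidase inhibitor, was at 247% and Aqp1 at 210% of scrambled, with log2 fold changes of 1.09 and 0.98. The other protein-coding genes with large rises rested on 1 scrambled library each. The 9530068E07Rik gene was at 1.62 and 9.23 FPKM in scrambled and 11.5 and 16.2 in siMEF2A, and its adjusted p was 0.306 without scrambled replicate 1. Katna1, a subunit of the microtubule-severing enzyme katanin, was at 17.3 and 2.94 FPKM in scrambled and 23.2 and 18.3 in siMEF2A, and its adjusted p was 0.724 without scrambled replicate 2. Both calls were also lost under each of the 3 other scalings, without a filter on low values (0.105 and 0.249) and with robust moderation (1.0 for both).

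The remaining named genes were features of fewer than 300 bases, whose FPKM is unstable. Gm22620 was listed at 0 in both scrambled libraries and at 4.33 and 8.69 FPKM in siMEF2A, and Gm26347 at 4.14 and 4.12 FPKM in scrambled and 0 in both siMEF2A libraries. Gm23245 and Gm24888, like Gm22620 small nucleolar RNAs, were listed at 0 in scrambled replicate 2 alone, and without it their adjusted p was 0.282 and 0.787. Gm23865, a small nuclear RNA, was at 0 in siMEF2A replicate 1 alone and at 3723 FPKM in the other, and its adjusted p was 0.994 without that library. The calls of Gm23245, Gm24888 and Gm23865 were also lost under each of the 3 other scalings, without a filter on low values (0.157, 0.273 and 0.263) and with robust moderation. Gm25752, annotated as a microRNA, was at 202% of scrambled, with an adjusted p of 0.0909 under quantile normalization. Gm26191 and Gm22405 had nearly the same FPKM as each other in each library, at 30.1% and 30.3% of scrambled, so their reads cannot be assigned with certainty, and under quantile normalization their adjusted p was 0.127 and 0.137 (0.0518 for Gm22405 under median-ratio scaling, and 1.0 for both with robust moderation). Gm14173 fell from 3.75 ± 0.201 to 0.0167 ± 0.0173 FPKM, but it is a processed pseudogene of 278 bases with 98.2% identity to the ribosomal protein gene Rpl37a, so its value is uncertain. Without genes that had only short or small RNA transcripts, an alternative added after the data were seen, 72 genes were higher and 170 lower.

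Sarcomere genes fell in 29 of 40 cases and rose in 0, and 34 fell when adjusted over the list alone. After Myl4, Myoz2 and Smpx, the smallest p belonged to Myh3, which fell from 41.5 ± 4.64 to 13.7 ± 1.96 FPKM (log2 fold change -1.53, SE 0.16, limma adjusted p = 4.24e-08). The median log2 fold change of the list was -0.86, and camera gave an adjusted p of 7.26e-98 with the preset correlation and an adjusted p of 0.388 with an estimated correlation. The members furthest above 0 were Tpm3 and Tmod4, at log2 fold changes of 0.20 and 0.15 that did not pass.

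Excitation-contraction coupling genes fell in 12 of 31 cases and rose in 0, and 14 fell and 1 rose when adjusted over the list alone. The calcium-binding calsequestrins of the sarcoplasmic reticulum fell, Casq1 to 7.94% and Casq2 to 36.3% of scrambled (log2 fold changes -1.54 and -1.37). The Casq1 percentage rests on low FPKM, where a ratio of FPKM shows a larger change than the log2(FPKM + 1) scale. Srl, the gene of sarcalumenin, fell to 46.4%. Camk2a, a calmodulin-dependent kinase gene, fell to 40.3%. The list had a median log2 fold change of -0.34 and a camera adjusted p of 2.41e-23, and an adjusted p of 0.685 with an estimated correlation. Of 14 genes of the acetylcholine receptor and neuromuscular junction, 4 fell and 0 rose, and 8 fell when adjusted over the list alone. The receptor subunit genes Chrng, Chrnd and Chrnb1 fell to 53.4%, 60.4% and 65.4% of scrambled and Nes, the intermediate filament gene nestin, to 63.6%. Without siMEF2A replicate 1 none of these 4 calls held (limma adjusted p from 0.0711 for Chrng to 0.795 for Nes), and the Chrnb1 call was lost without each of the other 3 libraries as well (0.0523 to 0.0822) and the Nes call without scrambled replicate 2 (0.0885). Quantile normalization ended the calls of Chrnd (0.0590), Nes (0.106) and Chrnb1 (0.0831). Testing without a filter on low values ended those of Nes (0.0656) and Chrnb1 (0.0703), and the Chrnb1 call was lost with small RNA symbols kept (0.0571) and without a trend (0.0507). The camera adjusted p of this list was 1.95e-10, with an adjusted p of 0.685 under an estimated correlation. Of 35 costamere and dystrophin complex genes 7 fell and 0 rose, and 10 fell when adjusted over the list alone. Itgb1bp2, the integrin-binding protein melusin, fell to 30.7% and Cav3, the muscle caveolin, to 19.4% of scrambled. Cav3 was also at low FPKM, with a log2 fold change of -1.06. Csrp3, the muscle LIM protein, fell from 2.76 ± 0.205 to 0.774 ± 0.301 FPKM. Camera gave an adjusted p of 1.28e-13 for that list and an adjusted p of 0.685 with an estimated correlation.

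**Figure D2:**
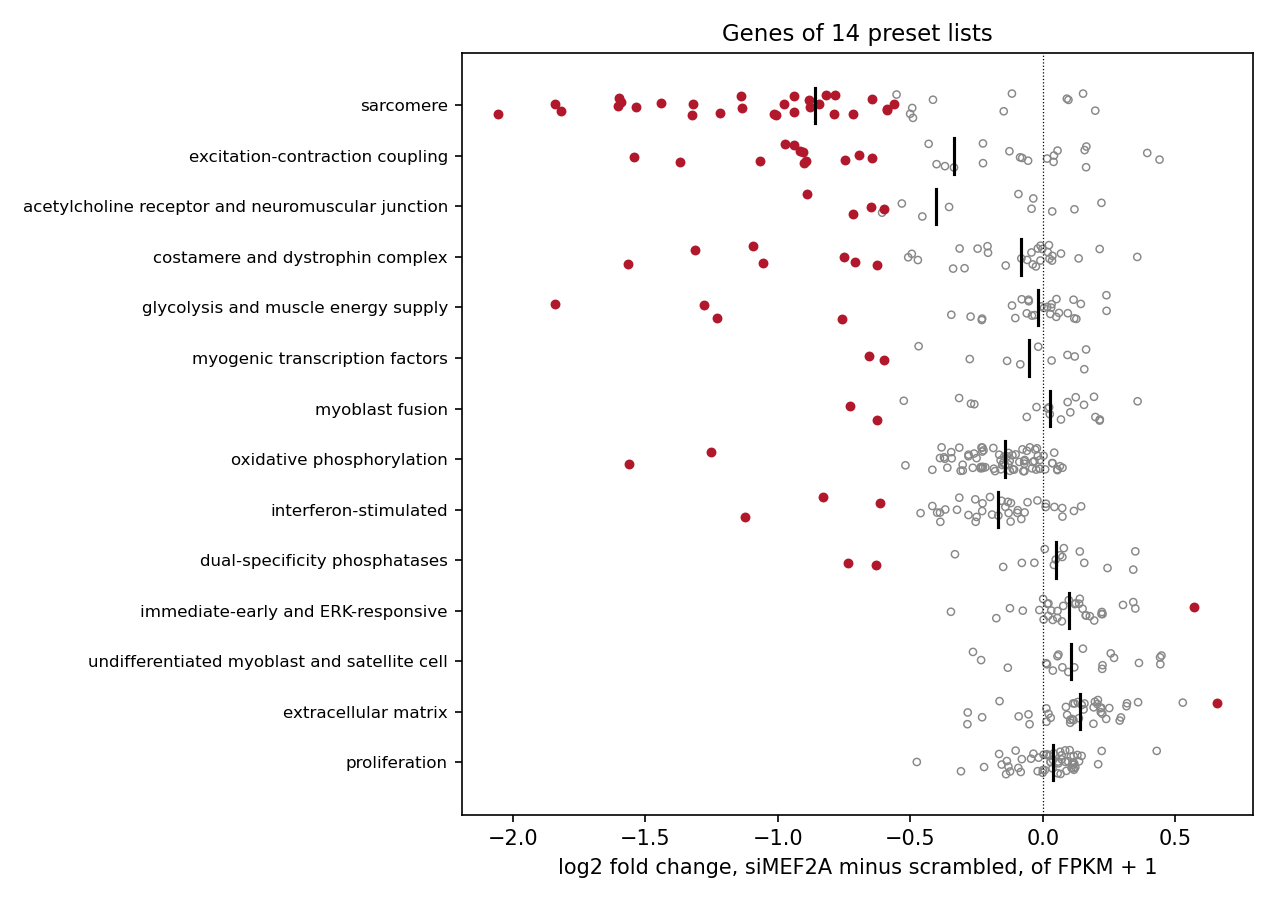
Log2 fold change of FPKM + 1, siMEF2A minus scrambled, of each tested gene of 14 lists fixed before the data were examined (filled points passed at a limma adjusted p under 0.05, open points did not, black bars are list medians, n = 2 libraries per group). Filled points are the 29 sarcomere genes and 12 excitation-contraction coupling genes that fell and smaller numbers elsewhere, and the proliferation and undifferentiated lists have none.

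Among 32 genes of glycolysis and muscle energy supply, 4 fell and 0 rose, also when adjusted over the list alone. Besides Mb they were Ckm, the muscle creatine kinase, from 42.8 ± 2.44 to 17.1 ± 0.788 FPKM, Pgam2, the muscle phosphoglycerate mutase, at 36.2% of scrambled, and Pygm, the muscle glycogen phosphorylase, at 49.1%. The Pygm call was lost without siMEF2A replicate 1 (limma adjusted p = 0.0529). Camera gave an adjusted p of 3.55e-05 and, with an estimated correlation, an adjusted p of 0.832, and the list's median log2 fold change was -0.02. The camera call of this list was lost without scrambled replicate 2 (adjusted p = 0.0900, median 0.10). Of 76 oxidative phosphorylation genes 2 fell and 0 rose, the same adjusted over the list alone, and both encode muscle isoforms of cytochrome c oxidase subunits: Cox6a2 fell to 28.2% and Cox8b to 39.4% of scrambled. Camera gave this list an adjusted p of 1.45e-10 and an adjusted p of 0.781 with an estimated correlation, and without siMEF2A replicate 2 the adjusted p was 0.149 with a median of -0.012. Replicates of a group differed by more than the groups did. The list's median difference was -0.22 for scrambled 2 minus 1 and -0.25 for siMEF2A 2 minus 1, against -0.14 between the groups. Between same-numbered libraries it was -0.092 for siMEF2A 1 minus scrambled 1 and -0.18 for siMEF2A 2 minus scrambled 2. It was -0.36 for siMEF2A 2 minus scrambled 1 and 0.063 for siMEF2A 1 minus scrambled 2. These values do not tell an effect of the siRNA from variation between libraries, whose differences also went with transcript length, as given at the end.

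Among 12 myogenic transcription factor genes 2 fell and 0 rose, and 3 fell when adjusted over the list alone. Myog, which encodes myogenin and is switched on as myoblasts differentiate, went from 132 ± 8.75 to 83.4 ± 4.04 FPKM (log2 fold change -0.66, SE 0.17, limma adjusted p = 0.0287), and Tead4 fell to 61.4% of scrambled. Myod1 was at 71.6% with an adjusted p of 0.172. The Myog and Tead4 calls were lost without scrambled replicate 2, siMEF2A replicate 1 or siMEF2A replicate 2 (0.127 to 0.466 for Myog and 0.0650 to 0.427 for Tead4), and the Myog call under quantile normalization (0.0922). Without a filter on low values both were lost (0.0516 for Myog and 0.0698 for Tead4). Camera gave the list an adjusted p of 0.00798 and an adjusted p of 0.832 with an estimated correlation, and the call was lost without scrambled replicate 2 (0.201) or siMEF2A replicate 1 (0.312). Of 21 myoblast fusion genes 2 fell and 0 rose, and 3 fell when adjusted over the list alone. They were Tmem8c, the fusion protein myomaker, from 98.5 ± 16.8 to 58.8 ± 3.41 FPKM, and Gm7325, the small fusion protein myomixer, from 45.4 ± 4.14 to 29.0 ± 0.375 FPKM. Both were lost under quantile normalization (0.0809 and 0.0837) and without any of 3 libraries, which for Tmem8c were scrambled replicate 2 and both siMEF2A replicates (0.0547 to 0.238) and for Gm7325 scrambled replicate 1 and both siMEF2A replicates (0.180 to 0.261). Camera gave the fusion list an adjusted p of 0.155 in the lower direction, with a median log2 fold change of 0.026 and a mean of -0.048, and the list was called lower without scrambled replicate 1 (0.00410) and at a minimum mean of 5 FPKM (0.0111). With an estimated correlation its adjusted p was 0.834.

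In limma, 0 of 20 genes of the undifferentiated myoblast and satellite cell list passed, also when adjusted over the list alone, and 4 were higher at an unadjusted p under 0.05. Camera called that list higher at an adjusted p of 0.0492 (adjusted p = 0.832 with an estimated correlation), with Cd34, Cav1 and Vcam1 at 137%, 137% and 135% of scrambled, but the call was lost without each library in turn (0.0758 to 0.406) and under quantile normalization (0.0577). It was also lost with small RNA symbols kept (0.0507), without short features (0.0617) and from protein-coding transcripts alone (0.0886). Between replicates the list's median differed by 0.14 for scrambled and 0.12 for siMEF2A (2 minus 1), against 0.11 between the groups. Of 56 proliferation genes 0 passed in limma, with 0 also adjusted over the list alone and 2 at an unadjusted p under 0.05, and E2f2, at 69.4% of scrambled, had the smallest p (limma adjusted p = 0.169). Camera placed the proliferation list in the lower direction at an adjusted p of 0.752, whereas its median log2 fold change was 0.04. Of 15 cell cycle exit genes 0 passed in limma and 3 were lower at an unadjusted p under 0.05, and 2 fell when adjusted over the list alone. In that list Gadd45b was at 67.5% and the cyclin-dependent kinase inhibitor gene Cdkn1a at 69.2% of scrambled (limma adjusted p = 0.108 and 0.175, camera adjusted p = 0.0686 for the list, and 0.0452 under median-ratio scaling, 0.0466 under upper-quartile scaling and 0.0356 at a minimum mean of 5 FPKM, and 0.685 with an estimated correlation).

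Of 42 extracellular matrix genes 1 rose and 0 fell, also when adjusted over the list alone. Vcan, the proteoglycan versican, went from 10.8 ± 3.40 to 17.3 ± 3.01 FPKM (limma adjusted p = 0.0369), and the call was lost under each of the 3 other scalings (0.150 to 0.248) and without scrambled replicate 1 (1.0) or siMEF2A replicate 2 (0.666). The Vcan call was also lost with a pseudocount of 0.1 (0.0528), without a filter on low values (0.152), with small RNA symbols kept (0.0815) and without a trend (0.0795). Camera called the matrix list higher at an adjusted p of 0.0216 (adjusted p = 0.834 with an estimated correlation), and the direction turned without scrambled replicate 1, where the list's median was -0.068. The call was also lost without siMEF2A replicate 2 (adjusted p = 0.576) and without a filter on low values (0.0777). The list's median difference was 0.42 for scrambled 2 minus 1 and 0.37 for siMEF2A 2 minus 1, larger than the 0.14 between the groups. Between same-numbered libraries it was 0.19 for siMEF2A 1 minus scrambled 1 and 0.096 for siMEF2A 2 minus scrambled 2. It was 0.53 for siMEF2A 2 minus scrambled 1 and -0.22 for siMEF2A 1 minus scrambled 2. As the labels do not say which libraries pair, an effect of the siRNA is not told from variation between libraries. Of 26 TGF-beta and BMP signalling genes 0 passed in limma and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.0577, and 0.834 with an estimated correlation), and this list was called higher under median-ratio (0.0452) and upper-quartile (0.0466) scaling, and without scrambled replicate 2 (0.0131) or siMEF2A replicate 1 (0.00631). Of 17 insulin-like growth factor genes 2 fell and 0 rose, and 3 fell when adjusted over the list alone. Igf2, a growth factor of fetal tissue and differentiating muscle, went from 13.6 ± 1.13 to 6.60 ± 1.70 FPKM (log2 fold change -0.96, SE 0.16, limma adjusted p = 0.000203). Its imprinted neighbour H19, a long noncoding RNA, went from 729 ± 89.4 to 348 ± 65.6 FPKM (log2 fold change -1.07, SE 0.21, limma adjusted p = 0.00226), a call lost without siMEF2A replicate 1 (0.299) and under quantile normalization (0.0594). Camera gave that list an adjusted p of 0.0984, with a median of 0.02 and a mean of -0.09, and it was called lower without scrambled replicate 1 (0.0118) or siMEF2A replicate 2 (0.0190) and at a minimum mean of 5 FPKM (0.0111). Its adjusted p was 0.834 with an estimated correlation.

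Interferon-stimulated genes fell in 3 of 39 cases and rose in 0, and 4 fell when adjusted over the list alone. Oas2, an enzyme that senses double-stranded RNA, fell from 2.96 ± 0.218 to 0.818 ± 0.0127 FPKM, Bst2, the antiviral membrane protein tetherin, from 126 ± 17.5 to 70.4 ± 3.85 FPKM, and Ifi44 to 60.3% of scrambled. The Bst2 call was lost without siMEF2A replicate 2 (limma adjusted p = 0.0790), and the Ifi44 call under each of the 3 other scalings (0.0531 to 0.0873) and without scrambled replicate 2 (0.529), siMEF2A replicate 1 (0.395) or siMEF2A replicate 2 (0.0551). Without a filter on low values (0.131), with small RNA symbols kept (0.0710) and without a trend (0.0748) the Ifi44 call was lost too. Camera gave the list an adjusted p of 6.45e-12 and an adjusted p of 0.761 with an estimated correlation. Its median log2 fold change was -0.17, and -0.018 without scrambled replicate 2, where the median of all genes was 0.090 against 0.045 with all libraries. Of 27 unfolded protein and amino acid stress genes 0 passed in limma and 5 were lower at an unadjusted p under 0.05 (camera adjusted p = 0.275 in the lower direction, median 0.09, mean -0.01), and 1 fell when adjusted over the list alone, the stress hormone gene Fgf21, at 67.4% of scrambled. Fgf21 passed over all genes at a minimum mean of 5 FPKM (limma adjusted p = 0.0340), with robust moderation (0.0228) and without short features (0.0239). It also passed from protein-coding transcripts alone (0.0430) and with the replicate block (0.00688). Its log2 fold change was -0.54 with all libraries and -0.64 without scrambled replicate 1. Of 29 apoptosis and p53 target genes 0 passed in limma and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.474).

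Markers of other cell types were few. Of 9 adipocyte markers 1 rose, Lpl, lipoprotein lipase, from 1.17 ± 0.382 to 2.31 ± 0.465 FPKM (limma adjusted p = 0.0299, camera adjusted p = 0.752 for the list), and the call was lost under each of the 3 other scalings (0.124 to 0.239) and without scrambled replicate 1 (0.765) or siMEF2A replicate 1 (0.273). It was also lost with a pseudocount of 0.1 (0.0507), without a filter on low values (0.0687), with small RNA symbols kept (0.0597) and without a trend (0.0672). Adjusted over the list alone, 1 rose and 1 fell, the latter being Fabp4, the fatty acid-binding protein of adipocytes, from 1.92 ± 0.541 to 0.975 ± 0.293 FPKM (log2 fold change -0.56, limma adjusted p = 0.0619 over all genes). Of 8 smooth muscle and myofibroblast markers 2 fell and 0 rose, and 3 fell when adjusted over the list alone. They were Tagln, the actin-binding protein transgelin, at 57.5% of scrambled, lost without siMEF2A replicate 1 (0.0534), and Actg2, enteric gamma-actin, at 58.6%, lost without scrambled replicate 2 (0.0563) or siMEF2A replicate 2 (0.0660). Camera gave that list an adjusted p of 0.000114 and an adjusted p of 0.711 with an estimated correlation. None of 3 bone and cartilage markers, 4 cardiac markers or 1 neural, blood or endothelial marker passed in limma, with 1, 0 and 0 at an unadjusted p under 0.05, and these lists were too short for camera. The 9 genes of the Gtl2-Dio3 imprinted locus were not analysed here.

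Of 82 ribosomal protein genes and 10 replication-dependent histone genes 0 passed in limma, with 0 adjusted over each list alone and 0 at an unadjusted p under 0.05. Both families have near-identical copies that can share reads, so their values are uncertain. Camera called the ribosomal protein list lower at an adjusted p of 0.0314 (adjusted p = 0.834 with an estimated correlation), and the direction turned under quantile normalization and without scrambled replicate 1 or siMEF2A replicate 2, where the medians were 0.028, 0.10 and 0.093. The call was also lost under median-ratio (0.150) and upper-quartile (0.0768) scaling, without a filter on low values (0.0615) and without short features (0.0617). Between replicates the list's median differed by -0.36 for scrambled 2 minus 1 and by -0.31 for siMEF2A 2 minus 1, against -0.048 between the groups. Ribosomal protein genes took 30.2% and 25.4% of the FPKM of matched longer transcripts in scrambled replicates 1 and 2, and 28.5% and 25.2% in siMEF2A replicates 1 and 2. Camera called the histone list lower at an adjusted p of 0.0216 (adjusted p = 0.685 with an estimated correlation), a call lost without scrambled replicate 1 (0.430), siMEF2A replicate 1 (0.240) or siMEF2A replicate 2 (0.0912).

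Signs of RNA or library quality differed between libraries within and between the groups. RP23-81C12.3, chosen after its values were seen, overlaps over 1245 of its 1831 bases with the ribosomal RNA-related gene Rn18s-rs5 on chromosome 17. It was at 2223 and 1491 FPKM in scrambled and 929 and 502 FPKM in siMEF2A (limma adjusted p = 0.00168), and that call was lost without siMEF2A replicate 2 (0.441) and under median-ratio (0.0979) or upper-quartile (0.0553) scaling. Across 11353 genes outside the muscle lists, the log2 fold change between groups and transcript length had a Spearman's rho of 0.262. Between the replicates of a group, the same rho was 0.432 for scrambled 2 minus 1 and 0.554 for siMEF2A 2 minus 1, and between single libraries of the 2 groups it ran from -0.366 for siMEF2A 1 minus scrambled 2 to 0.516 for siMEF2A 2 minus scrambled 1, and genes are not independent replicates.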

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

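Alternatives that removed genes with short or small RNA transcripts alone, summed protein-coding transcripts or tested single transcripts were chosen after the data had been seen. Under 17 alternatives Mef2a stayed lower and past the threshold, with log2 fold changes from -1.20 to -0.89, and Dusp6 stayed higher at 0.28 to 0.41 (limma adjusted p from 0.0401 to 1.0). Among 161 other values, 2440 of 2679 recalculated ones kept their call or stayed uncalled, 171 lost the call, 63 gained it and 5 turned. A turn was counted only for values called at first or under the alternative, so uncalled ones could change direction. The turned ones were the ribosomal protein list (median 0.028 under quantile normalization, 0.10 without scrambled replicate 1 and 0.093 without siMEF2A replicate 2) and the matrix list (-0.068 without scrambled replicate 1 and 0.00022, with camera in the lower direction, without siMEF2A replicate 2). With 1 library left out, the medians ran from -0.23 to 0.10 for the ribosomal and from -0.068 to 0.35 for the matrix list. The cause was not tested.

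The number of higher genes, 48, depended on the processing more than the 156 lower ones. It was 13 under median-ratio, 14 under upper-quartile and 11 under quantile scaling, 28 with a pseudocount of 0.1, 29 without a filter, 23 with small RNA symbols kept, 24 without a trend, 73 with robust moderation, 76 at an adjusted p under 0.1 and 76 from protein-coding transcripts alone. Lower genes numbered 99 at a minimum mean of 5 FPKM, where fewer genes were tested. Testing 23600 transcripts one by one called transcripts of 7 genes higher and 36 lower, of which 1 and 31 were among the gene-level calls. With 1 library left out, the lone library of its group being assumed to vary like the others, 41 to 74 genes were higher and 137 to 159 lower. Causes were not tested. Lists called higher, 2 at first, numbered 4 under median-ratio and 4 under upper-quartile scaling, 1 under quantile normalization, 1 with small RNA symbols kept, 1 without short features, 1 from protein-coding transcripts and 0 to 2 with 1 library left out. Lists called lower, 11 at first, numbered 14 at a minimum mean of 5 FPKM and 9 to 11 with 1 library left out. Camera with an estimated correlation and fry, which tests against no change and not against other genes, each called 0 lists higher and 0 lower; at an unadjusted p under 0.05 each had 1 list, the sarcomere one.

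Libraries of the groups share the numbers 1 and 2, but the labels do not say that they pair. The deviations of same-numbered libraries from their group means correlated at 0.292 across genes. The matrix list's median moved by 0.42 (scrambled) and 0.37 (siMEF2A) from replicate 1 to 2, and the ribosomal list's by -0.36 and -0.31. Among the lists compared this way, only the histone list went opposite ways (-0.077 and 0.070). The labels name no batch, but a difference shared by libraries of the same number is possible. The unblocked test takes no account of it, and leaving out 1 library would unbalance it. With the replicate block, 217 genes were higher and 291 lower, 4 lists were higher, and Dusp6 passed at an unmoved log2 fold change of 0.34 (adjusted p = 0.0401). Of the 161 other values, 24 gained and 0 lost the call under the block.

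Estimated depth relative to scrambled replicate 1 was 0.849 and 0.847 in the siMEF2A libraries. The simulated recovery of 49.3% at 1.5-fold also limits what these libraries can show.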

Other observations

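The other scalings and the leaving out of single libraries were fixed as alternatives before the data were seen. Of the bounds against which results were judged in this part, only those of the test on transcript length and level were set before the result was seen, and the genes of the next 2 paragraphs were chosen after their values were seen.

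The genes named here rose outside the lists and are a selection from those called. The matrix metalloproteinase gene Mmp3 went from 3.51 ± 0.0519 to 7.11 ± 0.0167 FPKM (SD, n = 2 each, log2 fold change 0.85, limma adjusted p = 0.000372), and Mmp13, a collagenase, was at 155% of scrambled. Spon2, a secreted matrix protein, was at 181%, Sod3, the extracellular superoxide dismutase, at 184%, Enpp2, the enzyme autotaxin, at 171%, and Dkk2, a modulator of Wnt signalling, at 187% of scrambled. Slpi, a secreted protease inhibitor, was at 174%. The Mmp3 call held without each library in turn and under each scaling. Without scrambled replicate 1 the calls of Mmp13, Spon2, Sod3, Enpp2 and Dkk2 were lost (limma adjusted p from 0.0763 to 0.992), without siMEF2A replicate 1 those of Mmp13, Slpi and Enpp2 (0.114 to 0.927), and without siMEF2A replicate 2 that of Mmp13 (0.149). Each of the 3 other scalings ended the calls of Mmp13 (0.0986 to 0.166) and Slpi (0.127 to 0.203), and quantile normalization that of Sod3 (0.0543). Without a filter on low values the calls of Mmp13 (0.124) and Slpi (0.0704) were lost, and that of Mmp13 also with a pseudocount of 0.1 (0.0528), with small RNA symbols kept (0.0736) and without a trend (0.0810).

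Other genes outside the lists fell. Chi3l1, a chitinase-like glycoprotein, went from 2.66 ± 0.177 to 0.667 ± 0.0175 FPKM (log2 fold change -1.14, limma adjusted p = 3.07e-06), and Ptgds, a prostaglandin D2 synthase, fell to 47.2% of scrambled. Fabp3, the fatty acid-binding protein of heart and muscle, fell to 29.5%. Of genes known to respond to interferon but not on the list, Ifi27l2a fell from 192 ± 15.2 to 66.0 ± 22.1 FPKM (log2 fold change -1.56, limma adjusted p = 1.04e-06), Tgtp2, an interferon-induced GTPase gene whose reads are uncertain because of its close copy Tgtp1, to 53.9% and Zbp1, a sensor of nucleic acids, to 62.2% of scrambled. The Zbp1 call was lost without scrambled replicate 2 (limma adjusted p = 0.0885) or siMEF2A replicate 2 (0.733) under quantile normalization (0.0956) and without a filter on low values (0.0611), and the Tgtp2 call from protein-coding transcripts alone (0.231).

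The fall of 29 of 40 sarcomere genes was set against 3 explanations. Scaling between the libraries was argued against, since the median log2 fold change of the list nearest to 0 under the 3 other scalings was -0.88. A trend on transcript length and expression level was also argued against as the whole cause, because the median residual of the 40 genes after such a trend, fitted on 11353 genes outside the muscle lists, was -0.91 (quartiles -1.23 and -0.58). A smaller share of differentiated cells in the siMEF2A wells cannot be told apart from lower expression per cell: log2 fold changes of the members had an SD of 0.57 against a median standard error of 0.16, but the level of each gene in undifferentiated cells is not known from these libraries. The loss of MEF2A is the biological explanation that the design names. With 1 siRNA preparation against Mef2a, an effect of that preparation on other transcripts may also contribute.

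An effect of the siRNA on other transcripts was examined as a hypothesis of its own, that genes fell through seed matches of the siRNA in their 3' UTRs. Among 15082 sequences of 7 bases, 0 occurred in at least 50% of the 117 lower genes with an annotated 3' UTR and at least 1.5 times as often as in the other genes searched. The largest excess, of ACACGGG in 7.69% of the lower genes against 2.76% of others, was equalled or passed in 68 of 100 random sets of genes of similar 3' UTR length. Direct matches of 1 shared 7-base seed in the 3' UTRs of most of the lower genes were argued against. Seed effects on a few genes stay open, as the siRNA sequence was not used here. The search could not decide on falls that follow indirectly from such a gene, or on several seeds.

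Features under 300 bases or of small RNA type alone made up 24 of the 204 called genes. Of 100 such genes tested 24.0% were called, against 1.54% of 11724 others (two-sided Fisher's exact test p = 3.14e-21, where genes are not independent replicates). Unstable FPKM of features shorter than a fragment is a candidate explanation: their within-group SD was 3.47 times that of other genes of the same mean level. A response of small RNAs to the siRNA was not tested.

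Interferon-stimulated genes were lower in siMEF2A for 32 of 39 members. That one library carries most of the difference stays open. The list's median log2 fold change was -0.018 without scrambled replicate 2, against -0.17 with all libraries, but the median of all genes moved as well, from 0.045 to 0.090. Relative to the median of all genes the list was at -0.11 (bootstrap SE over members 0.042) without that library and at -0.21 with all of them. Camera called the list lower without that library (adjusted p = 0.0195, and 2.52e-15 to 0.0195 over the 4 libraries left out) with the preset correlation, while with all libraries the adjusted p was 0.761 with an estimated correlation. In fry, which tests the list against no change and not against other genes, the adjusted p was 0.626. Between single libraries the median difference was -0.12 for siMEF2A 1 minus scrambled 1, -0.42 for siMEF2A 1 minus scrambled 2, 0.039 for siMEF2A 2 minus scrambled 1 and -0.24 for siMEF2A 2 minus scrambled 2. Between replicates it was 0.25 for scrambled 2 minus 1 and 0.17 for siMEF2A 2 minus 1. An unequal interferon response to the 2 siRNA preparations cannot be told apart from an effect of Mef2a silencing, because there was 1 preparation of each kind.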
